A study of Mus musculus with 2 samples.

How the data were processed

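The samples were limbs of mouse embryos at embryonic day 15.5, strain B6NCrl, with male and female embryos pooled, per the labels. The assay was chromatin immunoprecipitation with sequencing (ChIP-seq) with an antibody against H3K9ac, acetylation at lysine 9 of histone H3. The labels give 1 group with 2 biological replicates, with limbs of 78 embryos in replicate 1 and of 62 embryos in replicate 2. They give the replicates different biosamples but the same donor label. Taking them as separate pools of embryos was a reading made here from the biosamples and the numbers of embryos. No second tissue, stage or antibody was part of the series, so no test between groups was made and the comparisons are of the replicates with each other and of sets of genes and peaks within the group.

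The authors called peaks on each replicate alone and on both replicates pooled, and derived a further list of replicated peaks from the pooled list and both replicate lists, per the notes deposited beside the peaks. All 4 lists are on mm10. The aligner, the peak caller, their versions and thresholds, and the treatment of reads that map to more than 1 place are not given in the sources used here. The labels name a possible control, which was not used here. Each peak carries a fold enrichment, which is a ratio over background as deposited by the authors, and a −log10 p and a −log10 q, also as deposited by the authors. The summit offset of each peak is likewise the authors' value. Fold enrichment was used to describe, rank and filter peaks, to compare sets of peaks or genes within a list by permutation, and to compare the replicates by rank correlation and ratio. The lowest −log10 p of the authors was 2.35 in the replicated list, so the list reaches down to weak peaks.

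Read counts were not in the files used, so the depth of the libraries is unknown and no interval rests on it. Intervals given with shares of peaks or genes are 95% Wilson intervals, and those with summit positions are exact Clopper-Pearson intervals. They cover counting error only, since neighbouring peaks and genes are not independent.

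Genes and transcription start sites (TSSs) came from the GENCODE M21 basic annotation of GRCm38, the assembly that mm10 names. Chromosome lengths and promoter sequence came from the RefSeq copy of GRCm38.p6, and no peak ended beyond the end of its chromosome. A protein-coding gene was called marked when a peak overlapped the window of 1 kb either side of any of its annotated TSSs. Where several peaks did, the gene took the highest fold enrichment and the greatest width among them. A peak was called shared when peaks of the other list covered at least 50% of its length. Chance levels came from 100 circular shifts of a list along each chromosome. Promoter CpG ratio was the observed over expected CpG count in 500 bp either side of the outermost 5′ end of the gene. Coordinates are 1-based on mm10. Peaks off the chromosomes, 8 of them in the replicated list, were left out of everything that used genes.

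Lists of genes were tested with a two-sided Fisher's exact test of marked members against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 22 lists. Odds ratios had 0.5 added to each cell. A comparison within quintiles of promoter CpG ratio used an exact conditional test with a Mantel-Haenszel odds ratio, to which nothing was added. The ratios with and without quintiles therefore differ in part by this term, most where nearly none or nearly all members were marked. Differences in medians were tested by two-sided permutation, with 100000 resamples for TSS against other regions and 10000 for alternatives and for the widths of lists. Genes and peaks are not replicates, so these p-values describe this set of peaks. The 22 lists were fixed before the data were examined. They are Hox genes of the 5′ part of the A and D clusters (Hoxa9 to Hoxa13 and Hoxd8 to Hoxd13), of the B cluster and of the C cluster, limb patterning, limb mesenchyme with tendon and joint, chondrocyte, osteoblast, skeletal muscle, epidermis, endothelium, erythroid, macrophage and leukocyte, peripheral glia and melanocyte, hepatocyte, forebrain neuron, cardiomyocyte, pluripotency and germline, housekeeping, cell cycle, signalling by Wnt, BMP, FGF and Hedgehog, ribosomal protein, and olfactory receptor genes. Every listed gene was found in the annotation.

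The rule for named genes was also fixed before the data were examined. It takes the 10 genes with the highest fold enrichment at a TSS and the 10 with the widest region, up to 3 marked members of highest fold and up to 3 unmarked members of each list, all Hox genes of the 3 Hox lists, up to 5 genes per replicate marked in that replicate's own list alone, and the 5 replicated regions of highest fold more than 10 kb from any TSS. Other genes named as examples were chosen after their values were seen.

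Alternatives changed the overlap that counts as shared, the threshold on the authors' p or q, the TSS window (500 bp and 2 kb), the choice of TSS, the peak list, and the background genes. They were fixed before the data were examined, except for 3. A transcript set with more TSSs, the removal of peaks at several genes, and the joining of peaks within 500 bp were added after the data were examined. The functions were tested on simulated data. They recovered a simulated sharing of 39.8% of 20000 peaks. Among simulated lists of 20 genes made with an odds ratio of 0.2, 96% passed an unadjusted p of 0.05, against 6% of those made with an odds ratio of 1. Of simulated lists tied to strata but with no effect within them, 85% passed without strata and 1% within them. Their odds ratio within strata had a median of 0.806, where 1 was made. The power of the comparison within strata was not simulated, so a call that ends within CpG quintiles may end through low power. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.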

Results

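H3K9ac, a histone mark of active promoters, was mapped by ChIP-seq in limbs of mouse embryos at embryonic day 15.5. The series had 1 group with 2 biological replicates, with limbs of 78 embryos (replicate 1) and 62 embryos (replicate 2). The peak list of replicate 1 holds 54402 peaks over 23.9 Mb, with a median width of 257 bp, and that of replicate 2 holds 51625 peaks over 23.7 Mb, with a median width of 261 bp. Pooling both replicates gave 61225 peaks. The authors' list of replicated peaks holds 23499 of these, which cover 0.771% of the chromosomes at a median width of 738 bp. Sequencing depth is unknown, since the files hold peaks and not reads. All fold enrichments in this report are the authors' own values for single peaks.

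Srsf4, a splicing factor gene, had the highest fold enrichment at a TSS, 24.2 in the replicated list, with 22.4 in replicate 1 and 19.5 in replicate 2. Its region lay on chromosome 4 from 131873575 to 131875368, over the gene's 5′ end. Rpsa, which encodes a protein of the small ribosomal subunit, and Srsf6, a further splicing factor gene, both reached 23.4. Kmt5b, a histone methyltransferase gene, and Rbm39, a splicing regulator gene, both reached 23.0. Clk1, whose kinase phosphorylates splicing factors, and Map2k2, a kinase gene of the ERK pathway, both stood at 22.2. Adnp, Mbd2 and Rps20 followed at 21.5 each.

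Width picked out other genes. The widest region at a TSS, 6906 bp on chromosome 11 from 24075877 to 24082782, covered the start of Bcl11a, a transcription factor gene, and reached into the window of the neighbouring A830031A19Rik without covering its TSS. Prrx1, a homeobox gene of limb bud mesenchyme, had a region of 6550 bp on chromosome 1 from 163307561 to 163314110, at a fold of 14.6. Hoxd11 followed with 6205 bp, and Spry2, an antagonist of FGF signalling, with 6135 bp. Tnrc18 had 5545 bp, the semaphorin receptor gene Nrp2 5503 bp, and Col1a1, which encodes the main collagen of bone and tendon, 5220 bp. Hoxa10 had 4660 bp and Tbx15, a T-box gene, 4626 bp.

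In all, 13135 of 21938 protein-coding genes (59.9%, Wilson interval 59.2 to 60.5) were marked by a replicated peak within 1 kb of a TSS. The replicates' own lists marked 62.7% (replicate 1) and 62.4% (replicate 2), with a mean of 62.6% ± 0.193 (SD, n = 2). At marked TSSs the median fold was 8.78 (upper quartile 11.6) and the median width 1128 bp. For 2463 of the marked genes, 18.8%, the highest peak also lay at the TSS of another protein-coding gene, so that the peak could not be given to 1 of them. The share of marked genes rose with promoter CpG content, from 6.75% in the lowest quintile of CpG ratio through 25.8%, 76.3% and 93.8% to 96.7% in the highest.

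The replicates matched far more closely in strong than in weak peaks. Of the replicate 1 peaks, 40.6% (22103, Wilson interval 40.2 to 41.0) were shared with replicate 2, and of the replicate 2 peaks 41.6% (21468, interval 41.2 to 42.0) with replicate 1. Shifted lists gave means of 0.937% and 0.939%, and at most 1.10% and 1.13%. The lists had 14.7 Mb in common, a base-pair Jaccard index of 0.446 against 0.00507 for shifted lists. In the top decile by fold, 99.9% of the peaks of both replicates were shared, while in the lowest decile 9.13% of replicate 1 peaks and 8.85% of replicate 2 peaks were. Shared peaks of replicate 1 had a median width of 604 bp and a median fold of 5.52, against 210 bp and 2.89 for the others. The same medians in replicate 2 were 635 bp and 5.84 against 209 bp and 3.02. With both lists held to a −log10 q of 2 or more, sharing was 68.9% for replicate 1 and 59.0% for replicate 2.

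**Figure D1:**
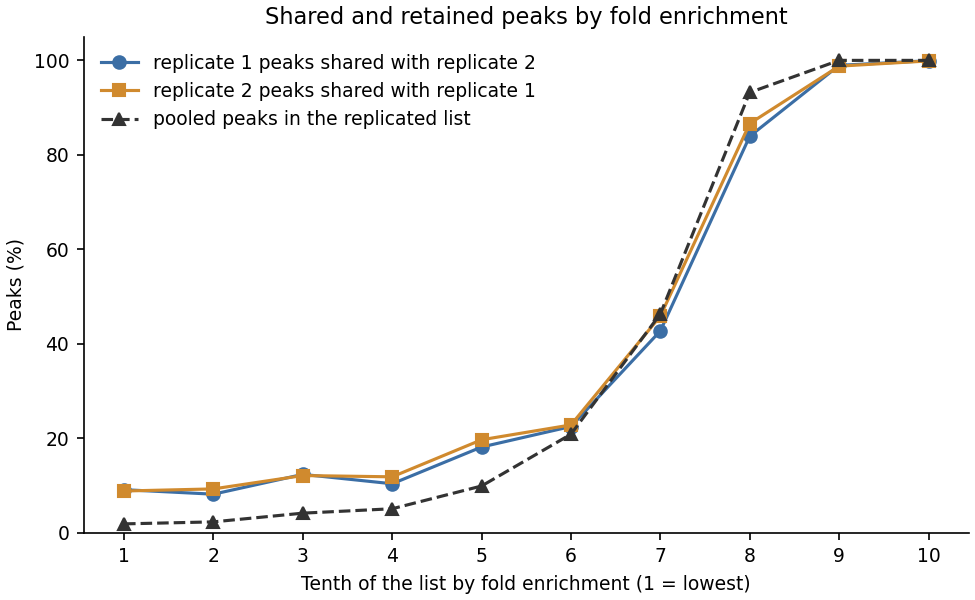
Percent of peaks (y axis) in each decile of fold enrichment (x axis, 1 is the lowest) that were shared with the other replicate (solid lines, replicate 1 circles, replicate 2 squares), or, for pooled peaks, were in the replicated list (dashed line, triangles). All 3 lines stay under 23% up to decile 6 and are at 98.8% or more in deciles 9 and 10.

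The promoters of 13135 genes were marked in both replicates' own lists, 12984 of them also by the replicated list. Across those 13135 genes, which are not independent replicates, the highest fold at the TSS had a Spearman rho of 0.872 between replicates. The log2 ratio of fold, replicate 1 over replicate 2, had a median of -0.06 and an SD of 0.32 over the 12984 genes, and 92.9% of them were within 1.5-fold. Genes marked in 1 replicate alone had low folds. Replicate 1 alone marked 620 genes, led among those outside the replicated list by Rsph3a at 4.74, Doc2g at 4.47, Myo15b at 4.42, Psrc1 at 4.38 and Plcb2 at 4.21. Replicate 2 alone marked 560, led by Zfp994, Tmem29 and Snorc, a cartilage proteoglycan gene, at 4.67 each, and by Exph5 and Jaml at 4.42 each.

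All 23499 of its peaks stood unchanged in the pooled list, of which they made up 38.4%. Peaks of each replicate covered at least 50% of the length of 18958 replicated peaks (80.7%). At 50% of either peak it was 21432 (91.2%), and 0 pooled peaks that met this condition were left out of the replicated list. Retention of pooled peaks rose from 1.89% in the lowest decile of fold to 46.3% in decile 7, 93.2% in decile 8 and 100% in deciles 9 and 10.

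Most replicated regions lay at promoters. Of 23491 regions on the chromosomes, 16626 (70.8%, Wilson interval 70.2 to 71.4) overlapped the window of 1 kb around a protein-coding TSS, against a mean of 3.08% and at most 3.53% for shifted regions. In the replicates' own lists, which hold more weak peaks, it was 38.9% (replicate 1) and 40.6% (replicate 2). Regions at a TSS were wider, with a median of 915 bp against 432 bp elsewhere, and had a higher fold, 7.15 against 3.34. Both differences had p = 1e-05 in a two-sided permutation test of medians, the smallest that 100000 resamples can give. The share at a TSS was 28.7% in the lowest decile of fold and 98.1% in the top decile. By summit, 68.6% of replicated peaks lay in a protein-coding promoter window, which holds 1.98% of chromosome bases. Introns held 14.6% of summits and 39.2% of bases, intergenic sequence 8.19% and 53.7%, coding exons 3.12% and 1.09%, and 3′ UTRs 0.873% and 1.12%.

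Summits lay mostly downstream of the TSS. Among 3970 marked genes with a single annotated TSS and a single replicated peak, the median summit was 211 bp downstream (quartiles 134 and 349 bp). Summits of 87.5% (exact interval 86.4 to 88.5) were downstream. Replicate 1 gave a median of 210 bp over 3178 genes and replicate 2 a median of 218 bp over 3207 genes.

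**Figure D2:**
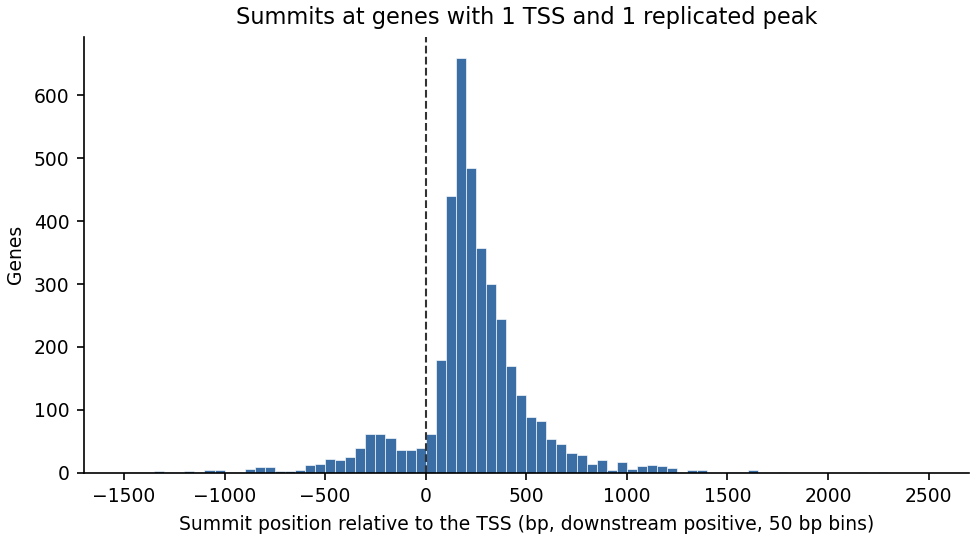
Number of genes (y axis) by the position of the replicated peak's summit relative to the TSS (x axis, bp, downstream positive, bins of 50 bp) for 3970 genes with 1 TSS and 1 replicated peak. The dashed line is the TSS, and most summits lie to its right, around the median of 211 bp.

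Genes that pattern the limb were marked more often than other genes. All but Shh and Fgf4 of the 30 limb patterning genes were marked (93.3%, adjusted p = 1.70e-04, Fisher's exact test). Gli3, the transcription factor of Hedgehog signalling that sets digit number and identity, had a fold of 14.6, with 14.2 in replicate 1 and 12.6 in replicate 2. Ptch1, the Hedgehog receptor, had 12.7, and Wnt5a, a ligand of limb outgrowth, 10.6. Tbx5 and Tbx4, T-box genes of forelimb and hindlimb, had 6.63 and 6.01, and Pitx1, a homeobox gene of the hindlimb, 7.42. Shh had a peak of fold 3.57 in replicate 2 alone, and Fgf4 had none in either replicate. The adjusted p was 0.115 within quintiles of promoter CpG ratio, at an odds ratio of 5.07 (95% interval 0.771 to 33.3) against 7.65 without them, and 0.116 with peaks of at least median fold, which marked 63.3%.

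All 32 signalling genes of the Wnt, BMP, FGF and Hedgehog pathways were marked (adjusted p = 8.24e-07, Fisher's exact test). Smo, the Hedgehog signal transducer, had a fold of 16.8, Id3, a target of BMP signalling, 16.1, and the BMP receptor gene Bmpr1a 15.6.

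Markers of limb mesenchyme, tendon and joint were marked in 16 of 20 cases, as were those of chondrocytes, with an adjusted p of 0.0871 for each by Fisher's exact test. Twist1, a regulator of mesenchyme, had a fold of 16.7, Prrx1 14.6 and Tcf7l2, a Wnt effector, 14.1. Tnmd and Lum, genes of mature tendon and connective tissue matrix, and Postn were not marked. Pth1r, the receptor that holds back chondrocyte maturation, had 11.3, and Sox9 and Sox6, transcription factors of cartilage, had 9.38 and 9.06. Col9a1, Matn1 and Cnmd were not marked. Within CpG quintiles the mesenchyme list passed the test, with an adjusted p of 0.0179. It also passed with peaks at several genes left out, at 75% (adjusted p = 0.0364, Fisher's exact test), and in the pooled list. Under the other alternatives it did not pass. It was at 85% without replicate 1 (adjusted p = 0.0529, Fisher's exact test) and at 70% at the outermost 5′ end (0.328). In the pooled list 90% and 95% of these 2 lists were marked (adjusted p = 0.0284 and 0.00887, Fisher's exact test), and without replicate 1 the chondrocyte list passed at 90% (adjusted p = 0.0218). The chondrocyte list also passed with windows of 2 kb, at 85% (adjusted p = 0.0471, Fisher's exact test). With peaks at several genes left out it passed at 80% (adjusted p = 0.012, Fisher's exact test). Under the other alternatives it did not pass. It was at 80% without replicate 2 (adjusted p = 0.194, Fisher's exact test). With peaks of at least median fold, 40% of it was marked against 47.7% of all genes (adjusted p = 0.512, Fisher's exact test). Within CpG quintiles its adjusted p was 0.0739 (exact test). The odds ratio there was 5.44 (95% interval 1.204 to 24.6) against 2.46 without quintiles. Within quintiles 12.3 of the 20 were expected to be marked, and without them 59.9% of other genes were. The higher ratio thus does not show a larger excess. Of 18 osteoblast genes, 11 were marked (61.1%, adjusted p = 1, Fisher's exact test). Within CpG quintiles 7.30 were expected, and the odds ratio was 3.29 (95% interval 1.13 to 9.56) against 1.03 without quintiles. That comparison fell just short of passing (adjusted p = 0.0531, exact test). Col1a1 had a fold of 10.6, Sparc, a bone matrix protein gene, 10.3 and Col1a2 9.22. Bglap, Ibsp and Spp1, matrix genes of mature bone, were not marked.

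All 10 Hox genes of the A and D list, which holds Hoxa9 to Hoxa13 and Hoxd8 to Hoxd13 and leaves out the genes further 3′, were marked (adjusted p = 0.0120, Fisher's exact test). Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had folds of 11.1, 11.4, 12.3 and 12.2. Hoxd8 to Hoxd12 had 6.67, 5.78, 5.91, 8.38 and 6.52, and Hoxd13 had 8.94 in replicate 1 and 9.33 in replicate 2. The region over Hoxa11 lay on chromosome 6 from 52243373 to 52247398, with a fold of 9.47 in replicate 1 and 12.7 in replicate 2. Of 10 HoxB genes only Hoxb2 was marked in the replicated list, at a fold of 2.70 (adjusted p = 0.00291, Fisher's exact test, lower). Hoxb1, Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8, Hoxb9 and Hoxb13 were not. Of 9 HoxC genes, 5 were marked (adjusted p = 1, Fisher's exact test), with low folds of 4.45 for Hoxc11, 3.97 for Hoxc8, 3.06 for Hoxc5, 2.70 for Hoxc4 and 2.53 for Hoxc10. Hoxc6, Hoxc9, Hoxc12 and Hoxc13 were not marked. Replicate 1's own list and the pooled list each marked 88.9% of HoxC genes, and replicate 2's own list 66.7%. The A and D list holds the 5′ part of its clusters, while the B and C lists hold their clusters nearly end to end, so the lists are not alike in position. Over the intervals of the named genes with 5 kb on each side, replicated peaks covered 68.7% of the HoxA interval, 41.7% of HoxD, 5.32% of HoxC and 0.691% of HoxB. The intervals spanned 47.8 kb in HoxA and 49.6 kb in HoxD, against 126 kb in HoxC and 184 kb in HoxB. These percents are thus not of like stretches.

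The HoxB call rests on the replicated list, where it held within CpG quintiles (6.87 expected, odds ratio 0.112, adjusted p = 1.68e-05, exact test). Replicate 1's own list marked 30% of HoxB genes (adjusted p = 0.0684, Fisher's exact test) and replicate 2's 40% (adjusted p = 0.234), and the pooled list marked 80% (adjusted p = 0.591), above the 64.8% of other genes. The HoxA and HoxD call had an adjusted p of 0.435 within CpG quintiles (exact test), where 8.56 marked genes were expected by chance. All 10 genes were marked, the highest count possible, and that count had p = 0.356 before adjustment (exact test). The comparison thus could not have passed this list as higher and does not test the call.

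**Figure D3:**
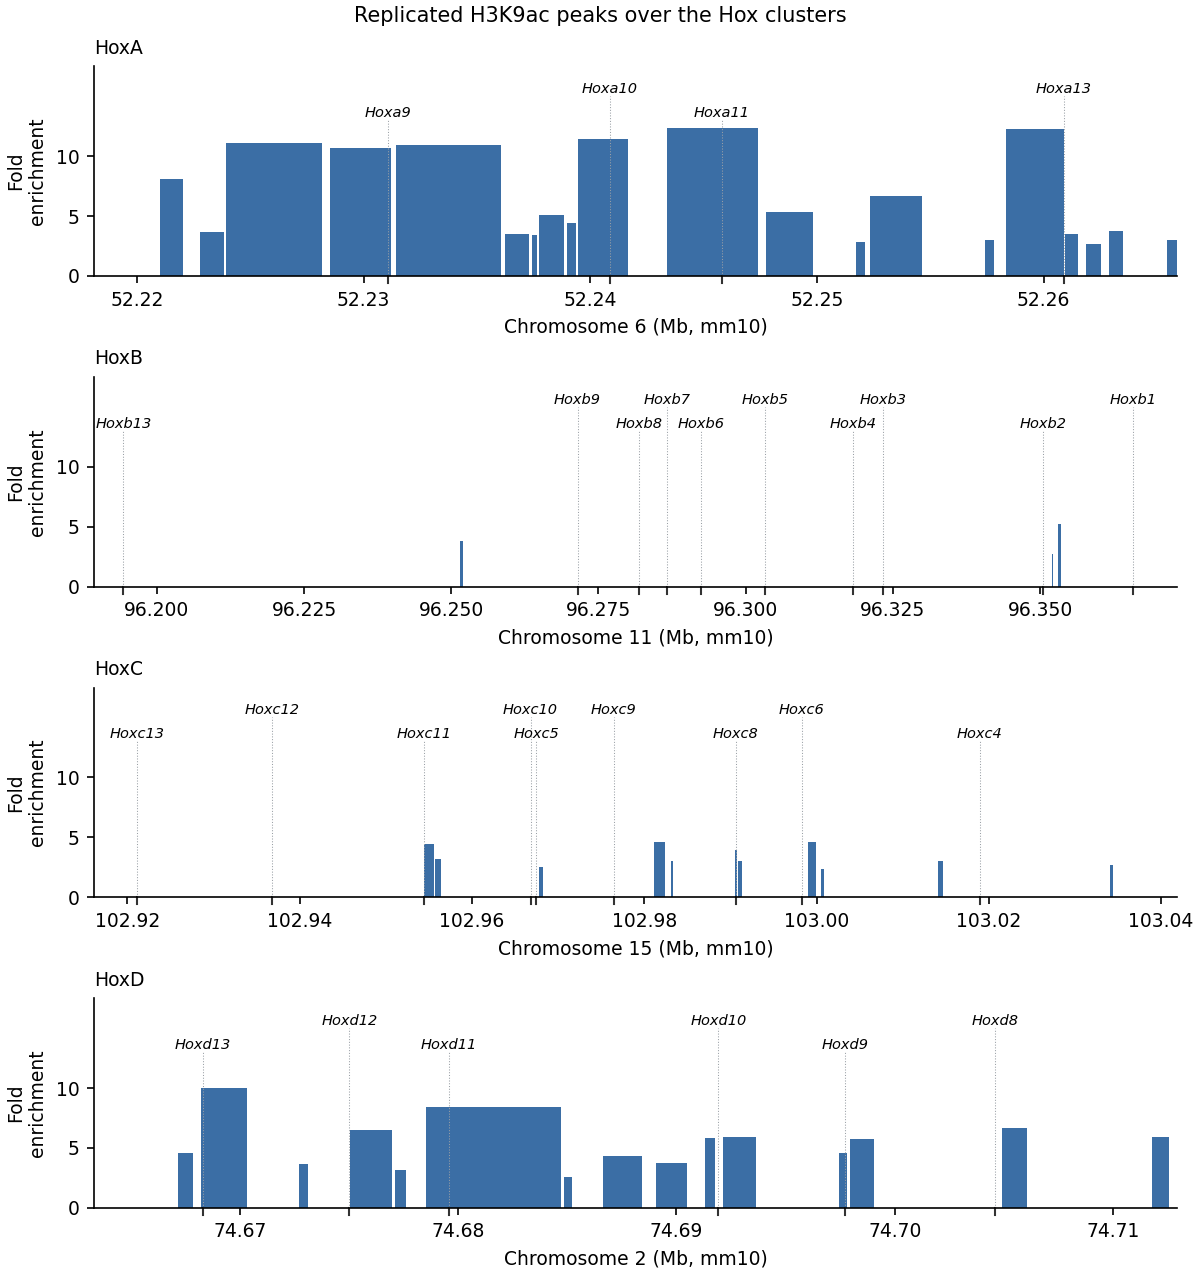
Fold enrichment (y axis, the authors' value) of each replicated peak, drawn to scale as a bar along the chromosome (x axis, Mb, mm10), over the listed genes of the HoxA, HoxB, HoxC and HoxD clusters. Dotted lines are the outermost annotated 5′ ends of the genes, and peaks reach a fold of 12.3 in HoxA, against 5.24 in HoxB and 4.61 in HoxC.

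Markers of other cell types of the limb were marked less often or no more often than other genes. Of 27 skeletal muscle genes, 7 were marked (25.9%, adjusted p = 0.00117, Fisher's exact test, lower). Myl4 at a fold of 15.6 and Mylpf at 12.7, both genes of myosin light chains, share their peaks with the neighbours Cdc27 and Tbc1d10b, and Mef2c, a muscle transcription factor gene, had 6.67. Myod1, Myf5 and Myf6, regulators of the muscle lineage, were not marked by the replicated list, though Myod1 had peaks of fold 2.63 and 4.39 in the replicates. The own list of each replicate marked 40.7% of muscle genes. The pooled list marked 55.6% (adjusted p = 0.390, Fisher's exact test), and within CpG quintiles the adjusted p was 0.0803. Of 16 endothelial genes, 5 were marked (31.2%, adjusted p = 0.0313, Fisher's exact test, lower). They were led by Prox1, a gene of lymphatic endothelium, at 6.20, Erg at 5.40 and Kdr, a VEGF receptor gene, at 4.46, while Pecam1, Cdh5 and Tek were not marked. That call ended without replicate 1 (adjusted p = 0.168, Fisher's exact test), without replicate 2 (0.164) and in the pooled list (0.380). It held within CpG quintiles, at an odds ratio of 0.105 against 0.320 without them (adjusted p = 0.0363, exact test). Within quintiles 8.88 of the 16 were expected to be marked, and without them 59.9% of other genes were. The lower ratio thus does not show a larger deficit.

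Blood genes were marked less often too. Of 15 erythroid genes, 4 were marked (26.7%, adjusted p = 0.0214, Fisher's exact test, lower), among them Klf1, a regulator of globin genes, at 7.72, Nfe2 at 4.73 and Gypa at 3.81. Hbb-bt, Hbb-bs and Hba-a1, globin genes with near-identical copies, were not marked. Within CpG quintiles 3.94 marked erythroid genes were expected and the adjusted p was 1. With peaks at several genes left out it was 0.154 (Fisher's exact test). Of 15 macrophage and leukocyte genes only Cd14 was marked, at 4.09 (6.67%, adjusted p = 1.15e-04, Fisher's exact test, lower), and Ptprc, Cd68 and Csf1r were not. The own lists marked 20% (replicate 1) and 26.7% (replicate 2) of them. Their adjusted p was 0.114 within CpG quintiles, at an odds ratio of 0.219 against 0.0692 without them. Epidermal genes were marked in 12 of 20 cases (adjusted p = 1, Fisher's exact test), with Klf4 at 10.3, Grhl2 at 6.52 and Tfap2a at 6.36, and without Krt5, Krt14 and Krt15. Genes of peripheral glia and melanocytes were marked in 7 of 14 cases (adjusted p = 0.680, Fisher's exact test). Mpz, at 12.3, shares its peak with Sdhc, Mbp had 7.63 and Mitf 6.26, and Sox10, Plp1 and S100b were not marked.

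Lists from tissues outside the limb were marked less often. Of 20 hepatocyte genes, Foxa3 alone was marked, at a fold of 12.2 in a peak shared with Sympk (5%, adjusted p = 1.97e-06, Fisher's exact test), and Alb, Afp and Apoa1 were not. Within CpG quintiles the adjusted p was 0.0531 (exact test), and 4.91 of the 20 were expected to be marked. Without quintiles, 59.9% of other genes were marked. The odds ratio was 0.0571 within quintiles and 0.0514 without them. Only the latter has 0.5 added to each cell, so with 1 member marked the 2 ratios do not show how much CpG content matters. Replicate 1's own list marked 20% of the hepatocyte genes. Of 21 forebrain neuron genes, 5 were marked (23.8%, adjusted p = 0.00227, Fisher's exact test), led by Emx2 at 6.49, Slc17a7 at 5.56 and Gabra1 at 4.93, while Syn1, Syt1 and Snap25 were not. The own list of each replicate marked 38.1% of them, and the pooled list 47.6% (adjusted p = 0.164, Fisher's exact test). Of 16 cardiomyocyte genes, 3 were marked, Ryr2 at 6.99, Scn5a at 4.13 and Irx4 at 3.50 (18.8%, adjusted p = 0.00227, Fisher's exact test), and Nkx2-5, Nppa and Nppb were not. Replicate 1's own list marked 37.5% of them (adjusted p = 0.0910, Fisher's exact test) and replicate 2's 31.2%. Of 16 pluripotency and germline genes, Dazl at 4.13 and Esrrb at 3.18 were marked (12.5%, adjusted p = 3.21e-04, Fisher's exact test), and Pou5f1, Nanog and Zfp42 were not. Of 1135 olfactory receptor genes, Olfr94 alone was marked, by a peak of fold 2.33 (0.0881%), and the own lists marked 0.793% (replicate 1) and 0.529% (replicate 2) of these genes.

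Genes in use in most cells and genes of the cell cycle were nearly all marked. The 20 housekeeping genes were all marked (adjusted p = 1.47e-04, Fisher's exact test), with Actb at 20.7, Ywhaz at 19.4 and Eef1a1 at 19.1. So were all 19 cell cycle genes (adjusted p = 1.93e-04, Fisher's exact test), with Aurka, in a peak shared with Cstf1, at 15.9, Ccnd2 at 11.3 and Mcm6 at 10.6. The adjusted p of the cell cycle list was 0.441 within CpG quintiles (exact test), where 17.4 marked genes were expected. With all 19 marked no higher count was possible, so that comparison could not have passed the list as higher. Of 83 ribosomal protein genes, 80 were marked (96.4%, adjusted p = 1.64e-13, Fisher's exact test), with Rpsa at 23.4, Rps20 at 21.5 and Rps19 at 20.5. The other 3 were Rpl10l, Rpl39l and Rpl3l. In all, 6 of the 22 lists were marked more often than other genes, 10 less often, and 6 did not pass the test.

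**Figure D4:**
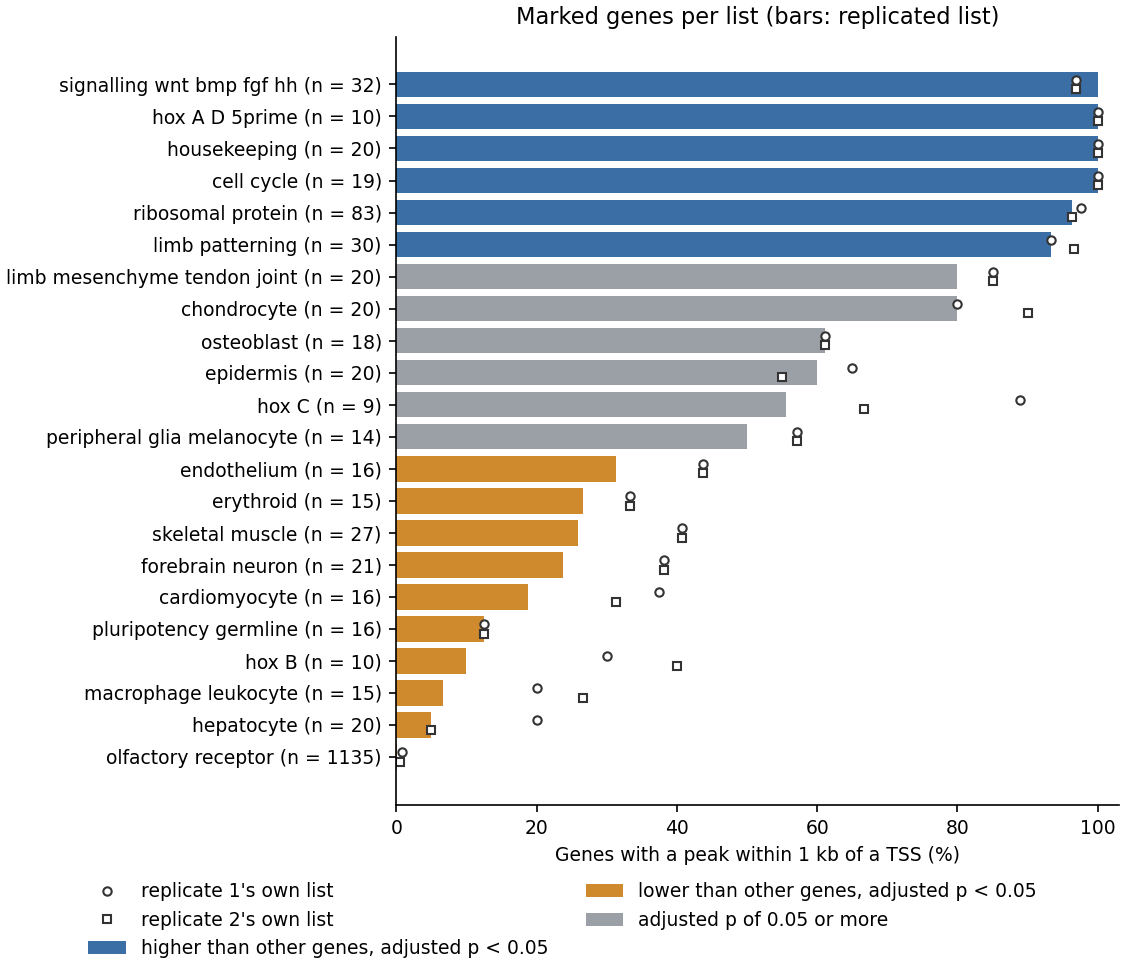
Percent of the genes of each list (y axis, with the number of genes) that have a peak within 1 kb of a TSS (x axis). Bars show the replicated list, colored by the test against all other protein-coding genes, and circles and squares show the own lists of replicate 1 and replicate 2. Bars run from 0.0881% for olfactory receptor genes to 100% for 4 of the lists.

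Regions far from promoters were fewer and weaker. Of the replicated regions, 1994 (8.49%) lay more than 10 kb from any TSS, at a median fold of 3.32 and a median width of 396 bp, and 1065 of them (53.4%) lay within a protein-coding gene. The highest, at a fold of 20.0, lay within Bicral on chromosome 17 from 46855608 to 46858792, 23294 bp from the nearest TSS. The next, at 18.0, was on chromosome 15 from 85669826 to 85673332, between genes and 62232 bp from the nearest protein-coding TSS, that of Ppara. A region of 15.8 lay between genes on chromosome 12 from 8640790 to 8641645, 32489 bp from Pum2. A region of 14.6 lay within Kalrn on chromosome 16 from 34572260 to 34574520, and a region of 12.7 between genes on chromosome 1 from 86487728 to 86488716, 38010 bp from Ptma. Both replicates held all 5 regions. The middle 1000 bp of each was rich in CpG. Those in Bicral and Kalrn lay within 1 kb of a TSS of the RefSeq annotation and of the transcript set with more TSSs.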

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

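The larger transcript set, the removal of peaks at several genes and the joining of peaks within 500 bp were settings added after the data were seen. No test between groups exists in this series, and depth is unknown, so what depth limits could not be measured. No paired analysis was possible because the series has 1 group. The shared percent of replicate 1 and replicate 2 peaks was 45.9 and 47.3 at an overlap of 1 bp, 32.3 and 34.0 at 50% of both peaks, 68.9 and 59.0 at a −log10 q of 2 or more, 70.1 and 69.3 at a −log10 p of 5 or more, and 79.2 and 77.3 for the top 20000 peaks. Lists of equal length gave 42.5 for replicate 1. The Jaccard index was 0.599 at that q and 0.452 for lists of equal length. Rho was 0.866 for windows of 500 bp. Replicated peaks found in both replicates were 91.6% at 1 bp, 91.2% at 50% of either peak and 66.2% with replicate lists held to that q. Of the weaker 50% of pooled peaks, 4.68% were retained when ranked by fold and 4.09% when ranked by p.

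Marked genes were 59.1% with windows of 500 bp, 60.7% with 2 kb, 57.1% at the outermost 5′ end, 64.8% with the pooled list, 47.7% with peaks of at least median fold, 60.8% with the larger transcript set, 49.3% without peaks at several genes, and 62.4% to 62.7% with 1 replicate left out. Regions at a TSS were 67.0% and 75.8% with windows of 500 bp and 2 kb, 74.9% with TSSs of all genes, and 38.9% to 40.6% with 1 replicate left out. In the last case the lists hold weak peaks that the replicated list leaves out. The median summit was 210 to 218 bp with 1 replicate left out. The cause of the other differences was not tested.

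Between 13 and 17 lists passed the test under every alternative but the comparison within CpG quintiles, where 10 did, 4 higher and 6 lower. The 6 lower were the HoxB, endothelial, forebrain neuron, cardiomyocyte, pluripotency and germline, and olfactory receptor lists. In that comparison the HoxA and HoxD list and the cell cycle list, with all members marked, could not have passed as higher. The endothelial call ended under most alternatives. With windows of 500 bp, the outermost 5′ end or a −log10 q of 2 or more, the share stayed at 31.2% and only the p crossed 0.05 (adjusted p = 0.0526, 0.0602 and 0.0516, Fisher's exact test). With peaks of at least median fold, HoxC genes, at 0%, and epidermal genes, at 20%, were called lower (adjusted p = 0.00576 and 0.0174, Fisher's exact test). In 2 lists with a call the direction turned without passing the test: HoxB genes, at 80% in the pooled list, and erythroid genes, at 26.7% within CpG quintiles against 3.94 of 15 genes expected. Lists without a call changed sides as well, such as HoxC genes, at 88.9% in the pooled list, and chondrocyte genes, at 40% with peaks of at least median fold. The difference of TSS from other regions in width and fold passed its test under every alternative run. No peaks within a list overlapped, so that merging them first changed nothing and tests nothing.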

Other observations

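The widths of list members, the genes reached by the pooled list alone, and the comparison of X-linked with autosomal TSSs within CpG quintiles were tests chosen after the results were seen. The comparison of distant regions with the full GENCODE M21 set was not fixed beforehand either. The other tests in this part were fixed before the result they measure was seen.

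Among marked genes, the median TSS region was 2346 bp wide for Hox genes of the A and D lists, 2039 bp for signalling genes, 1897 bp for limb mesenchyme, tendon and joint genes and 1794 bp for limb patterning genes, against about 1130 bp in random lists of the same sizes. All 4 had an adjusted p of 0.0006, two-sided permutation over 15 lists. Against random genes of the same deciles of fold these 4 lists stayed wider (adjusted p = 0.000375 each, permutation), and so did chondrocyte genes, with 1385 bp against 852 bp (adjusted p = 0.0006), and osteoblast genes, with 1367 bp against 922 bp (adjusted p = 0.0262). Ribosomal protein genes, with the highest median fold of the lists at 12.5, were 1483 bp wide, above random lists (adjusted p = 0.0006, permutation) but not shown to be wider than the 1398 bp of genes of the same fold (adjusted p = 0.328, permutation). Chondrocyte and osteoblast genes did not pass the test against random lists of any fold (adjusted p = 0.167 and 0.315, permutation), and the 5 marked HoxC genes, at 410 bp, were narrower than random lists without passing it (adjusted p = 0.0617, permutation). The 7 marked muscle genes, at 458 bp, were narrower than random lists (adjusted p = 0.0440, permutation), but did not pass against genes of the same fold (adjusted p = 0.0777, permutation).

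A hypothesis fixed before its test was that the wide regions of limb regulators follow from their fold alone. The 44 marked genes of the limb patterning and mesenchyme lists had a median width of 1808 bp, which was 774 bp above random genes of the same deciles of fold (p = 0.0001 by permutation, the smallest that 10000 resamples can give). Fold alone may thus not account for the width, and no other explanation was tested.

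Some genes outside the replicated list had weak peaks in the pooled list. It reached 7 of the 9 unmarked HoxB genes, namely Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8, Hoxb9 and Hoxb13, and 8 of the 20 unmarked muscle genes, among them Myod1, Pax3, Pax7 and Actc1, against 12.2% of other unmarked genes (adjusted p = 7.63e-05 and 0.00696, Fisher's exact test over 13 lists). Genes were not matched on promoter CpG ratio here. The other unmarked genes include 1134 olfactory receptor genes, of which 0.441% were reached. The median CpG ratio of the whole olfactory receptor list was 0.106, against 0.472 for HoxB and 0.313 for muscle. How far CpG content accounts for the excess was not tested. No other cell-type list passed as higher: the pooled list reached 5 of 16 unmarked forebrain neuron genes (adjusted p = 0.122, Fisher's exact test), 3 of 11 endothelial, 3 of 14 macrophage and leukocyte, 1 of 14 pluripotency and germline, and 0 of 7 osteoblast genes. Among genes near many regions more than 10 kb from a TSS, picked after their values were seen, Bcor and Ppara had 10 each and Smad7, an inhibitor of TGF-β signalling, had 8.

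Skeletal muscle genes were marked less often than other genes, with an odds ratio of 0.245 (95% interval 0.106 to 0.565). Within quintiles of promoter CpG ratio it was 0.374 (0.133 to 1.06), and the call ended partly because the ratio moved towards 1 and partly because the interval widened. An interval that reaches 1 had been set beforehand as enough for CpG content as the cause, which was too loose, since the interval holds both 1 and the ratio before correction and so does not decide. In the pooled list the odds ratio was 0.674 (0.320 to 1.42), just past the bound of 0.67 set beforehand for the threshold of the replicated list as the cause, yet the own lists of replicate 1 and replicate 2, which also hold weak peaks, had odds ratios of 0.414 and 0.419, closer to 1 than the replicated list, and kept the call by a small margin (adjusted p = 0.0488 and 0.0428, Fisher's exact test), so the verdict on the threshold was left open after these values were seen. No biological explanation was tested.

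Marked TSSs on the X chromosome had a lower fold than those on autosomes. In the highest quintile of promoter CpG ratio the median was 6.38 against 11.1, a ratio of 0.574, and in the next quintile 5.64 against 9.03, a ratio of 0.625. The gap was smaller in the other 3, with ratios of 0.727, 0.797 and, for 10 X genes in the lowest quintile, 0.816, which lay within the 0.547 to 1.69 of single autosomes. These ratios cover marked genes only, and X genes were marked less often than autosomal genes in every quintile. The shares were 82.8% against 96.9% in the highest quintile and 14.2% against 27.3% in the second lowest. How the unmarked X genes bear on the size of the gap was not tested. Single autosomes against the other autosomes never fell below 0.904 and 0.914 in the upper 2 quintiles, which argues against CpG content as the cause. A candidate explanation is the silent X chromosome of female cells. Genes known to escape silencing in mouse (Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1) had a median log2 fold 0.70 above other marked X genes of their CpG quintiles (p = 0.00121, permutation, 379 genes). Pbdc1, at a fold of 4.77, lay below those other genes. A copy on the Y chromosome or wide use of the escape genes remains open, as does background on the X, which was not measured. The pools also held male embryos, whose cells have a single X chromosome. Fewer copies of the X than of autosomes may lower the fold without silencing, and this was not tested.

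High-fold regions more than 10 kb from any TSS may be promoters that the annotation used does not list. Of the 199 regions in the top decile by fold, 39.7% lay within 1 kb of a TSS of the RefSeq annotation, against 12.5% of the other 1795 (p = 2.48e-19, Fisher's exact test). A CpG-rich sequence was found in 56.3% against 11.6% (p = 2.53e-44, Fisher's exact test). Of the top decile 67.8% had 1 or both, and the rest remain open. In the full GENCODE M21 set, which lists more TSSs than the basic set, 29.6% of the top decile lay within 1 kb of a TSS. Of the other regions 10.1% did (p = 1.19e-12, Fisher's exact test). For such regions the distance of more than 10 kb holds for the basic annotation only. No biological explanation was tested.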
